A study of Arabidopsis thaliana with 6 samples.

How the data were processed

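Transcript levels were measured by RNA sequencing in 6 libraries from roots of Arabidopsis thaliana (thale cress, ecotype Columbia, wild type, vegetative stage). Each of 3 groups had 2 libraries: a control group, plants exposed to aluminium oxide nanoparticles (nAl2O3) and plants exposed to ionic aluminium. Total RNA was extracted with Trizol and libraries were made with the NEBNext Ultra RNA kit for Illumina, per the labels' protocols. Libraries were grouped by their titles. The other labels of nanoparticle replicate 2 spell its compound nAl2O4, and it was kept in the nanoparticle group by its title. Doses, exposure times, growth medium and sequencing batches are not given in the sources used here. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

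The values are RPKM, reads per kilobase of gene model scaled to the library's total reads, 1 value for each of 24438 genes and 6 libraries, as deposited by the authors, and the unit was taken from the name of their table and checked against its values. The submitters' processing notes name TopHat2 2.0.12, HTSeq 0.6.0 and the genome build TAIR10 without their roles. Strand handling and the treatment of reads that match several genes are not given in the sources used here, so levels of near-identical family members (the RBCS and CAB genes, PIP2;2 and PIP2;3, IPS1 and AT4) and of overlapping or antisense genes are uncertain. No gene in the table was at 0 in every library, and no further scaling between libraries was visible in the RPKM values beyond the library total. 0 columns were left unmapped to a sample. The annotation of TAIR10.1 served only for symbols, products, neighbouring genes, transcript length and GC content. 23677 loci (96.9%) matched it, and no coordinates are printed because the annotation may differ from that behind the table.

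Whole reads were recovered from the RPKM steps. Within a gene the values are whole multiples of what 1 read is worth, and 1283 genes with annotated lengths gave the library totals. All 24438 genes then came out as whole reads in every library within a tolerance of 1e-06 reads. Where several multiples were possible, a larger one was taken only if the smallest gene length fell far below that of the annotated transcript, a rule set after the summed reads were seen. On simulated values with known reads, the method recovered 6 of 6 totals and the reads of 99.04% of 3954 genes. Totals were 14489392 and 13687455 reads for the control libraries, 13798049 and 14097641 for the nanoparticle libraries, and 12318429 and 14252671 for the ion libraries. A floor of 3 reads corresponds to an RPKM of 0.207 to 0.244 in a transcript of 1 kilobase. Intervals and floors cover counting error only. Folds quoted as such are ratios of reads per total over the 2 libraries of each group. Where a group had 0 reads the fold is a lower bound computed against 3 reads over that group.

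The test was limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with a pseudocount of 1. It covered 19648 genes (80.4%) with RPKM of at least 1 in at least 2 libraries. The 3 groups shared 1 fit with 3 residual degrees of freedom, and empirical Bayes moderation used a mean-variance trend with 3.81 prior degrees of freedom. Contrasts were two-sided, and Benjamini-Hochberg adjusted p under 0.05 counted as passed. Log2 fold changes are on the log2(RPKM + 1) scale, which understates changes of low genes, and are given ± the moderated standard error. Levels are RPKM means ± SD of 2 libraries. "Rose" and "fell" are used of genes that passed.

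Before the data were examined, 32 gene lists with 509 loci were fixed from textbook knowledge for roots exposed to aluminium, including markers of shoot tissue, root zones and cell types. Of these, 31 lists had at least 5 tested members, and the flavonoid list was not tested for want of members. Lists were tested with camera from limma at its preset correlation of 0.01, again with an estimated correlation between genes, and with fry, which asks whether a list's genes move one way on balance without reference to other genes. The form with an estimated correlation rests on the 3 residual degrees of freedom of the fit. A missing call there therefore does not show that a list's genes vary together. Adjusted p values of lists are over the 31 lists. Members past the gene test are counted over all genes tested and, in a separate count, adjusted over the list alone. Some genes stand in more than 1 list, such as EXPA18, XTH14 and MYB51. Members with 0 reads in a group moved a list's median only for the sulphate and root hair lists, whose medians with these members at their bound are given beside them.

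Named genes followed a rule written before the data were examined. For each comparison it took the 8 genes with the largest rise and the 8 with the largest fall among those past the test with a mean RPKM of at least 5 in the higher group and no overlap between the libraries of the 2 groups. Where fewer passed in a direction, those that passed were taken, and where none passed, the 5 with the smallest p that met the same conditions on level and overlap were taken and are said to miss the threshold. From each list that passed its set test, or that had at least 3 members past the gene test, the rule took up to 4 members with the smallest p, and it always took 7 aluminium tolerance genes (ALMT1, MATE, ALS3, ALS1, STAR1, STOP1 and STOP2). Genes of the plastid and mitochondrial genomes were left out of the first part and summarised as a group. Genes named outside this rule are said to have been chosen after their values were seen.

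The test was tried on simulated data with 200 changed genes among 19648 and the spread of these libraries. In the comparison of nanoparticle with control it recovered 16.7% of 2-fold and 89.9% of 4-fold changes, with 7.7 false calls on average over 20 simulations. For ion against control the shares were 21% and 89.6%, with 16.95 false calls. Even with all 200 changed genes called, 16.95 false calls exceed the share of calls that the threshold on adjusted p allows. The genes called for ion against control in the real data may therefore include a larger share of false calls than that threshold states. In the nanoparticle comparison a shifted list was called in 20 of 20 simulations, and 0.1 other lists on average. The simulated genes varied independently of each other. These simulations therefore cannot show how often camera at its preset calls lists whose genes vary together. Over the lists called in that comparison of the real data, estimated correlations ran from 0.07 (suberin) to 0.93 (aliphatic glucosinolate).

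Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a filter at RPKM 5, median-of-ratios scaling, rescaling to 1 total (TPM), quantile normalization, moderation without the trend or with robust settings, a fit of only the 2 groups compared, library quality weights, the replicate number as a block, an adjusted p under 0.1, a log2 fold change of at least 1, and leaving out each library in turn, where a group left with 1 library was assumed to vary like the others. After seeing the data a correction of each library for transcript length and GC content and limma's voom on the recovered reads were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.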

Results

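Root transcripts were compared between 2 libraries of a control group, 2 of plants given aluminium oxide nanoparticles and 2 of plants given ionic aluminium, in a design that sets the responses to the particulate and the dissolved form side by side. Each library held 12318429 to 14489392 recovered reads and 18499 to 18893 genes at an RPKM of at least 1. The first principal component took 70.9% of the variance and parted the ion libraries, at 87.7 and 90.2, from the other 4, at -51 to -39.7. The second took 19.4% and parted control replicate 2, at -68.4, from the other 5, at -9.3 to 28.8. Across genes, which are not independent replicates, the control libraries correlated at 0.9648, the nanoparticle libraries at 0.9927 and the ion libraries at 0.983, and control replicate 1 and nanoparticle replicate 1 at 0.9913. The SD between the libraries of a group was 0.45 on the log2 scale in control, 0.19 in nanoparticle and 0.298 in ion. The 4 ribosomal RNA genes in the table held 0.247% and 0.275% of the ion reads, 0.004% of those of control replicate 2 and 0.092% to 0.118% of those of the other 3 libraries. The 156 plastid and mitochondrial genes held 0.141% and 0.102% of the ion reads and 0.016% to 0.025% of the reads of the other 4 libraries.

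**Figure D1:**
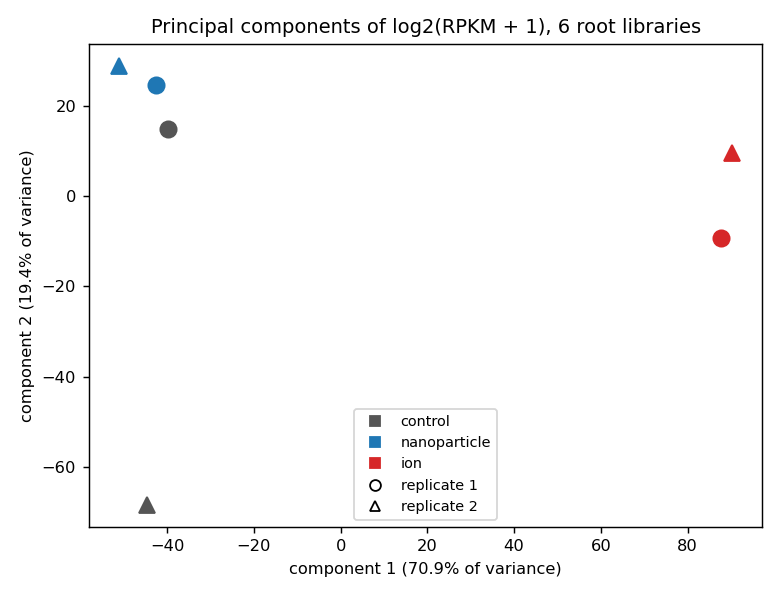
Each point is 1 of the 6 libraries on the first (x axis) and second (y axis) principal component of log2(RPKM + 1), with colours for the groups and shapes for the replicate numbers. The ion libraries lie at 87.7 and 90.2 on the first component and control replicate 2 at -68.4 on the second.

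Ionic aluminium against control asked which root transcripts respond to the dissolved metal. ALMT1 (AT1G08430), the malate transporter that releases malate to bind aluminium outside the root, stood at 239 ± 10 RPKM (SD, n = 2) in ion roots and 1.02 ± 0.137 in control roots, a 233-fold rise (log2 fold change 6.89 ± 0.2, limma adjusted p = 2.86e-05). MATE (AT1G51340), a citrate transporter, rose from 1.87 ± 0.435 to 11.2 ± 5.96 RPKM (2.0 ± 0.35, limma adjusted p = 0.00908). The polygalacturonase inhibitor PGIP2 (2.14 ± 0.22, adjusted p = 0.00142) and the transcription factor WRKY46 (1.74 ± 0.21, adjusted p = 0.00223) rose too. STOP1 (AT1G34370), the zinc finger factor that drives ALMT1, fell from 150 ± 42.5 to 64.4 ± 3.15 RPKM (-1.18 ± 0.23, limma adjusted p = 0.0143), and glutamate dehydrogenase GDH1 fell by 2.08 ± 0.28 (adjusted p = 0.00341). ALS1, a vacuolar half-size transporter, rose by 0.86 ± 0.2 (adjusted p = 0.0266), whereas ALS3 (0.35 ± 0.23, adjusted p = 0.307), STAR1 (-0.28 ± 0.23, adjusted p = 0.406) and STOP2 (0.49 ± 0.22, adjusted p = 0.151) did not pass. Of 18 tested members of the aluminium tolerance list, 5 rose, 5 fell and 8 did not pass, with the same 5 and 5 adjusted over the list alone. Their median was 0.33, camera did not set them apart from other genes (adjusted p = 0.433), and fry gave 0.00866. The calls of STOP1 (-1.23 and -1.13) and ALS1 (0.98 and 0.74) were lost without ion replicate 1 and without ion replicate 2, that of ALS1 also without either nanoparticle library (0.86), with TPM (0.75), in a fit of only the 2 groups and with library weights (both 0.86), and STOP2 passed without control replicate 2 (0.72). The list then had 4 that rose and 2 that fell without ion replicate 1 and 4 and 1 without ion replicate 2.

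**Figure D2:**
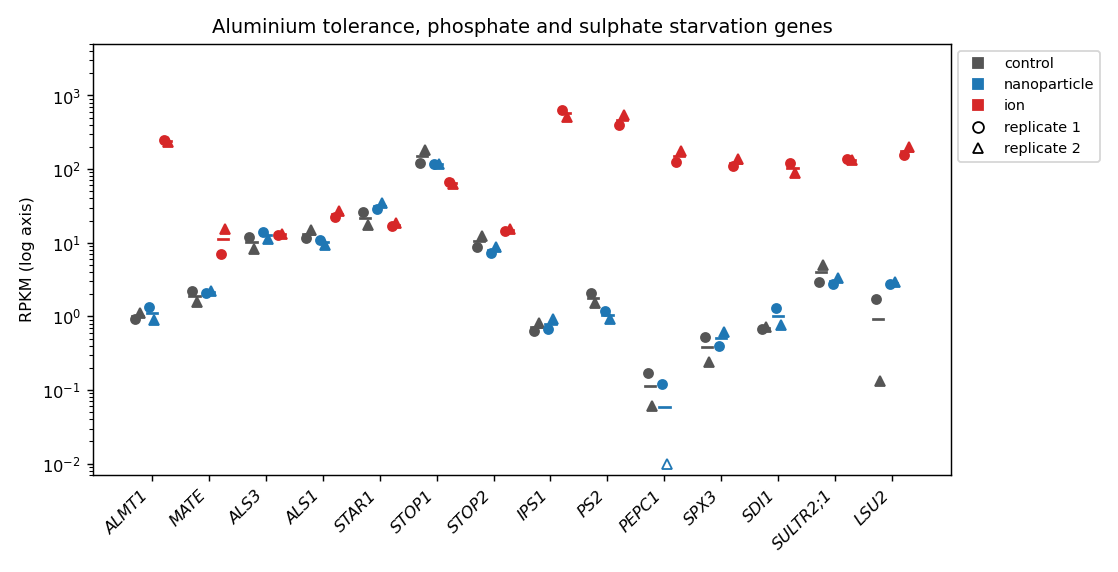
RPKM on a log axis for aluminium tolerance, phosphate starvation and sulphate starvation genes, with 1 point per library and a bar at the group mean; an open point drawn at 0.01 marks 0 reads. ALMT1 lies at 239 RPKM on average in the ion libraries and at 1.02 and 1.12 in control and nanoparticle.

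Genes of phosphate starvation rose almost throughout the list. Of 29 tested members, 26 rose, 0 fell and 3 did not pass, and 26 rose and 1 fell when adjusted over the list alone. The 3 were PHT1;1, PHT1;2 and PHO1, named after their values were seen. The phosphate transporter PHT1;3, outside the list and picked here after its values were seen, went the other way. It had 166 and 93 reads in control and 0 in both ion libraries, at least 81.4-fold lower. IPS1 (AT3G09922), a non-coding RNA that sequesters a phosphate microRNA, went from 0.723 ± 0.122 to 569 ± 91.6 RPKM (8.36 ± 0.2, limma adjusted p = 1.79e-05). The phosphatases PS2 (7.39 ± 0.23) and PEPC1 (7.07 ± 0.24) and the phosphate sensor SPX3 (6.48 ± 0.22) each had a limma adjusted p of 3.65e-05. The list median was 2.38 (camera adjusted p = 5.38e-17, fry 0.00308), and adjusted p = 0.476 with an estimated correlation. Without control replicate 1, control replicate 2 or ion replicate 2, 1 member fell.

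In the sulphate starvation list 11 of 13 members rose and 2 fell, also when adjusted over the list alone. SDI1 (AT5G48850), a repressor of glucosinolate synthesis under sulphur shortage, rose 148-fold (5.93 ± 0.24, limma adjusted p = 7.52e-05). The glutathione-degrading enzyme GGCT2;1 (5.91 ± 0.29, adjusted p = 0.000109), LSU2 (6.65 ± 0.4, adjusted p = 0.000236) and the vascular transporter SULTR2;1 (4.81 ± 0.24, adjusted p = 0.000117) rose. The 2 that fell were SULTR1;1 and SULTR1;2, transporters for sulphate uptake from the soil, named after their values were seen. SULTR1;1 had 0 reads in both ion libraries, at least 254-fold below control. The list median was 1.99, and 3.25 with members at 0 reads in a group at their bound (camera adjusted p = 1.32e-05, fry 0.000866), and adjusted p = 0.46 with an estimated correlation.

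Of the iron and nitrogen lists a minority of members passed. The vacuolar metal transporter IREG2 (AT5G03570) fell from 20.6 ± 11.3 to 0.817 ± 0.0646 RPKM (-3.47 ± 0.35, limma adjusted p = 0.0013). The regulator FIT (-2.25 ± 0.36, adjusted p = 0.00663), the reductase FRO2 (-2.2 ± 0.36, adjusted p = 0.00753) and the iron transporter IRT1 (-2.78 ± 0.46, adjusted p = 0.00753) fell as well. Of 27 members of the iron deficiency list 6 fell, 1 rose and 20 did not pass, with 6 and 1 adjusted over the list alone, at a median of -0.23 (camera adjusted p = 0.0629, fry 0.276). The nitrate transporter NRT2.1 (AT1G08090) fell by 4.35 ± 0.57 (limma adjusted p = 0.00313). Its partner NRT3.1 fell by 2.37 ± 0.36 (adjusted p = 0.0055), while nitrate reductase NIA2 rose (2.1 ± 0.29, adjusted p = 0.00399). The nitrogen list had 2 that rose and 3 that fell among 13, also adjusted over the list alone, a median of -0.38, camera adjusted p = 0.278 and fry 0.518. FIT was lost without ion replicate 2 (-2.1), FRO2 (-2.12 and -2.28) and IRT1 (-2.65 and -2.9) without either ion library and NRT3.1 without ion replicate 1 (-2.1). Of the iron list 2 members fell and 5 rose without ion replicate 1, 3 and 0 without ion replicate 2, 9 and 0 without control replicate 2, 5 and 3 without control replicate 1, and 5 and 0 without either nanoparticle library. Camera called it lower without control replicate 2 (adjusted p = 0.0101) and ion replicate 2 (9.95e-04), with a pseudocount of 0.1 (0.0338) and with a filter at RPKM 5 (0.0284), and the nitrogen list without control replicate 2 (0.0119). The nitrogen list had 4 rises and 3 falls without control replicate 1, 3 and 1 without ion replicate 1, and 1 and 2 without ion replicate 2.

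In the list of glutathione transferases and oxidative stress markers 11 of 16 rose and 0 fell (14 and 1 adjusted over the list alone). They included the kinase OXI1 (2.44 ± 0.21, limma adjusted p = 0.000809), GSTU4 (3.18 ± 0.33, adjusted p = 0.00138) and the zinc finger gene ZAT12 (2.29 ± 0.27, adjusted p = 0.00226). Its median was 1.33 (camera adjusted p = 2.25e-05, fry 0.0163), and adjusted p = 0.476 with an estimated correlation. Of 8 heat shock genes 7 rose and 0 fell, also adjusted over the list alone. They were led by HSP70-4 (3.15 ± 0.26, adjusted p = 0.000721) and HSFA2 (1.94 ± 0.24, adjusted p = 0.00233). Their median was 1.37 (camera adjusted p = 0.00131, fry 0.0064), and adjusted p = 0.476 with an estimated correlation. Without control replicate 2, either nanoparticle library or ion replicate 2 the first count was 7, and the heat shock count was 4 without ion replicate 2.

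In the jasmonate list 11 of 17 rose and 1 fell (12 and 2 adjusted over the list alone). The storage protein gene VSP2 (1.95 ± 0.17, limma adjusted p = 0.000779) and the repressors JAZ1 (1.9 ± 0.17, adjusted p = 0.000834) and JAZ5 (2.54 ± 0.23, adjusted p = 0.00089) rose, and JAZ9 fell by 1.61 ± 0.17 (adjusted p = 0.0015). The list median was 1.47 (camera adjusted p = 0.000621, fry 0.0102), and adjusted p = 0.476 with an estimated correlation. Among 17 salicylate and pathogen defence genes 8 rose and 2 fell, also adjusted over the list alone. Their median was 0.75 (camera adjusted p = 0.00364, fry 0.00515), and adjusted p = 0.476 with an estimated correlation. WRKY38 went from 0.521 ± 0.127 to 29.5 ± 9.43 RPKM (4.29 ± 0.26, limma adjusted p = 0.00025), GRX480 rose by 4.01 ± 0.26 (adjusted p = 0.000297) and ALD1, an enzyme of pipecolate synthesis, by 3.32 ± 0.22 (adjusted p = 0.000346). NIMIN1 stood at 33.6 ± 5.53 RPKM in ion and 0.128 ± 0.18 in control, where it had 2 reads. Without ion replicate 2 the jasmonate list had 7 that rose, and 1 salicylate gene fell without either ion library.

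In the root hair list 13 of 17 fell, 1 rose and 3 did not pass (14 fell and 2 rose adjusted over the list alone). The wall protein gene PRP3 (AT3G62680) went from 15.5 ± 4.89 to 0.258 ± 0.0266 RPKM (-3.68 ± 0.24, limma adjusted p = 0.00033). RHS19 (-3.76 ± 0.35, adjusted p = 0.000996) and the actin factor ADF8 (-3.14 ± 0.21, adjusted p = 0.000346) fell, and RHS2 rose (2.15 ± 0.25, adjusted p = 0.00199). The median was -1.97, and -2.03 with members at 0 reads at their bound (camera adjusted p = 3.65e-06, fry 0.0184), and adjusted p = 0.476 with an estimated correlation. Of 22 aquaporins 8 fell and 2 rose (11 and 2 adjusted over the list alone). PIP2;4 (AT5G60660) went from 171 ± 153 to 4.89 ± 0.923 RPKM (-4.52 ± 0.61, limma adjusted p = 0.00343) and PIP1;5 fell by 2.53 ± 0.35 (adjusted p = 0.00401). The list median was -1.18 (camera adjusted p = 0.00616, fry 0.202), and adjusted p = 0.745 with an estimated correlation. The control libraries differed in both lists, with control replicate 2 below control replicate 1 by a mean log2 difference of -0.64 over the root hair and -1.16 over the aquaporin genes. Without control replicate 1 the aquaporin list lost its camera call (adjusted p = 0.167), and 9 of its members fell and 5 rose. Without control replicate 2, 13 fell and 0 rose. Without either nanoparticle library 5 fell and 0 rose, and without ion replicate 1 and 2 the falls were 2 and 4. The root hair falls were 8 and 6 without ion replicate 1 and 2.

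In the secondary wall and xylem list 7 of 9 fell and 0 rose (8 fell adjusted over the list alone), among them the proteases XCP1 (-1.96 ± 0.17, limma adjusted p = 0.000834) and XCP2 (-1.51 ± 0.17, adjusted p = 0.00196) and the cellulose synthase CESA4 (-1.64 ± 0.21, adjusted p = 0.00273). The median was -1.42 (camera adjusted p = 2.25e-05, fry 0.0102), and adjusted p = 0.476 with an estimated correlation. Among 17 suberin and Casparian strip genes 8 rose and 1 fell, also adjusted over the list alone. The suberin genes KCS2 (2.88 ± 0.2, adjusted p = 0.000378), FAR4 (2.38 ± 0.24, adjusted p = 0.00121) and ABCG6 (1.94 ± 0.24, adjusted p = 0.00245) rose, while CASP5, which builds the Casparian strip, went from 7.54 ± 5.41 to 0.146 ± 0.206 RPKM (adjusted p = 0.0066). The list median was 0.69 (camera adjusted p = 0.00367, fry 0.0123), and adjusted p = 0.476 with an estimated correlation. Of 23 cell cycle and DNA replication genes 7 rose and 0 fell, also adjusted over the list alone, including PCNA1 (1.12 ± 0.17, adjusted p = 0.00548). Their median was 0.56 (camera adjusted p = 0.00192, fry 0.123), and adjusted p = 0.702 with an estimated correlation. Camera calls ended for suberin without control replicate 2 (adjusted p = 0.0515) and for the cell cycle without control replicate 1 (0.0506). Without ion replicate 1 and 2 the cell cycle count was 1 and 2, without either nanoparticle library 4 and without control replicate 2 it was 11. Xylem had 4 falls without ion replicate 1. Suberin had 4 rises without ion replicate 2, where the CASP5 call was lost (-2.56), and 2 falls without control replicate 2.

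Photosynthesis genes, listed as markers of shoot tissue, lay low in the ion roots and varied between libraries. Of 24 members 9 fell and 0 rose (22 fell adjusted over the list alone). The median was -1.83 (camera adjusted p = 1.4e-07, fry 0.135), and adjusted p = 0.695 with an estimated correlation. PSBO1, of the oxygen-evolving complex, went from 29.6 ± 7.4 to 7.76 ± 0.827 RPKM (-1.79 ± 0.28, limma adjusted p = 0.00628), and the antenna gene LHCB2.1 from 5.69 ± 0.728 to 0.355 ± 0.398 (adjusted p = 0.0157). Summed over the list, there were 5170 and 5037 reads in the control libraries, 2450 and 6491 in the nanoparticle libraries, and 1297 and 1390 in the ion libraries. Without ion replicate 1 and 2 the falls were 0 and 1, PSBO1 was lost without ion replicate 1 (-1.69) and LHCB2.1 without either (-2.03 and -2.64) and with library weights (-2.33), and without either nanoparticle library 21 fell.

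In all, limma called 4446 of 19648 genes (2418 higher and 2028 lower), 3226 of them with at least a 2-fold change on the log2(RPKM + 1) scale. The larger side turned with the scaling, at 2075 higher and 2294 lower with median-of-ratios, 2042 and 2371 with TPM, and 2068 and 2355 with quantile normalization. Besides the genes above, the largest rises were in AT5G20790 (7.94 ± 0.2), the methyltransferase gene HOL2 (7.69 ± 0.57), the methionine salvage gene ARD3 (7.4 ± 0.33), the phosphate-responsive RNA AT4 (7.14 ± 0.61) and AT5G38910 (7.11 ± 0.34), with limma adjusted p of 1.79e-05 to 0.000779. The largest falls were in AT5G26130, a CAP family gene at 154 ± 17.9 RPKM in control and 0 reads in ion (at least 683-fold lower), in AIR1 (-6.4 ± 0.5), AT5G56100 (-5.83 ± 0.25), the transporter UMAMIT17 (-5.59 ± 0.18), the aminotransferase AGT (-5.53 ± 0.24), AT1G33840 (0 reads in ion, at least 264-fold lower), the methyltransferase IGMT1 (-5.29 ± 0.19) and scpl2 (-5.12 ± 0.22). AT1G33840 lies in a run of 11 expressed loci on chromosome 1 of which 10 were near 0 in both ion libraries, with 26 ion reads over the run against 9792 in the other 4 libraries. The number called was 2758 with only these 2 groups in the fit, 2904 with library weights, 7732 without control replicate 1, 2754 and 2757 without nanoparticle replicate 1 and 2, and 2113 and 1865 without ion replicate 1 and 2.

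**Figure D3:**
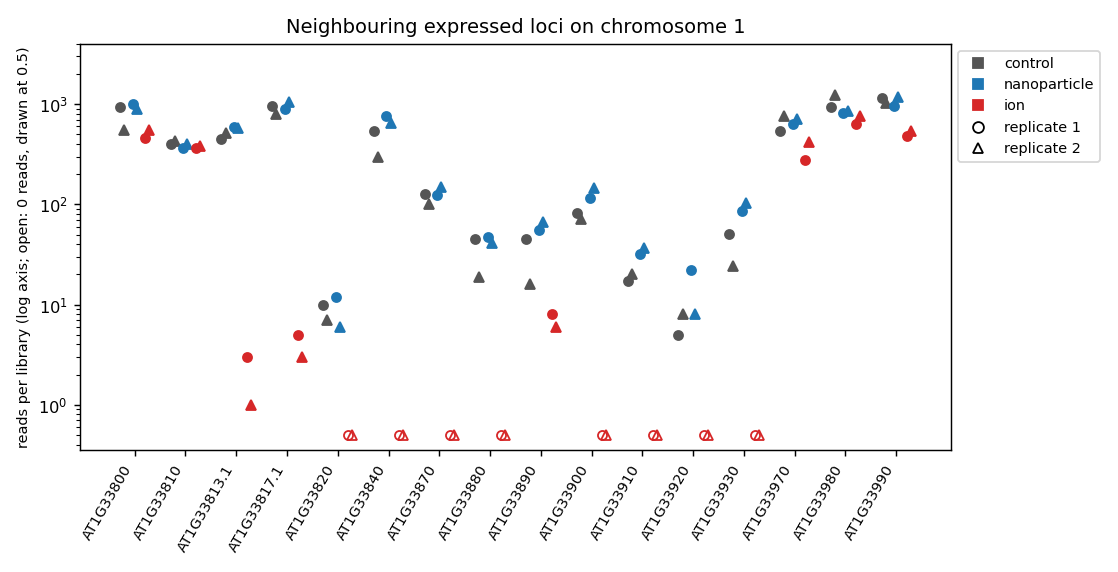
Reads per library (y axis, log scale) for neighbouring expressed loci on chromosome 1 in the order of the annotation (x axis), with 1 point per library coloured by group and an open point drawn at 0.5 for 0 reads. AT1G33840 has 0 reads in both ion libraries, while AT1G33810 to its left has 370 and 381.

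**Figure D4:**
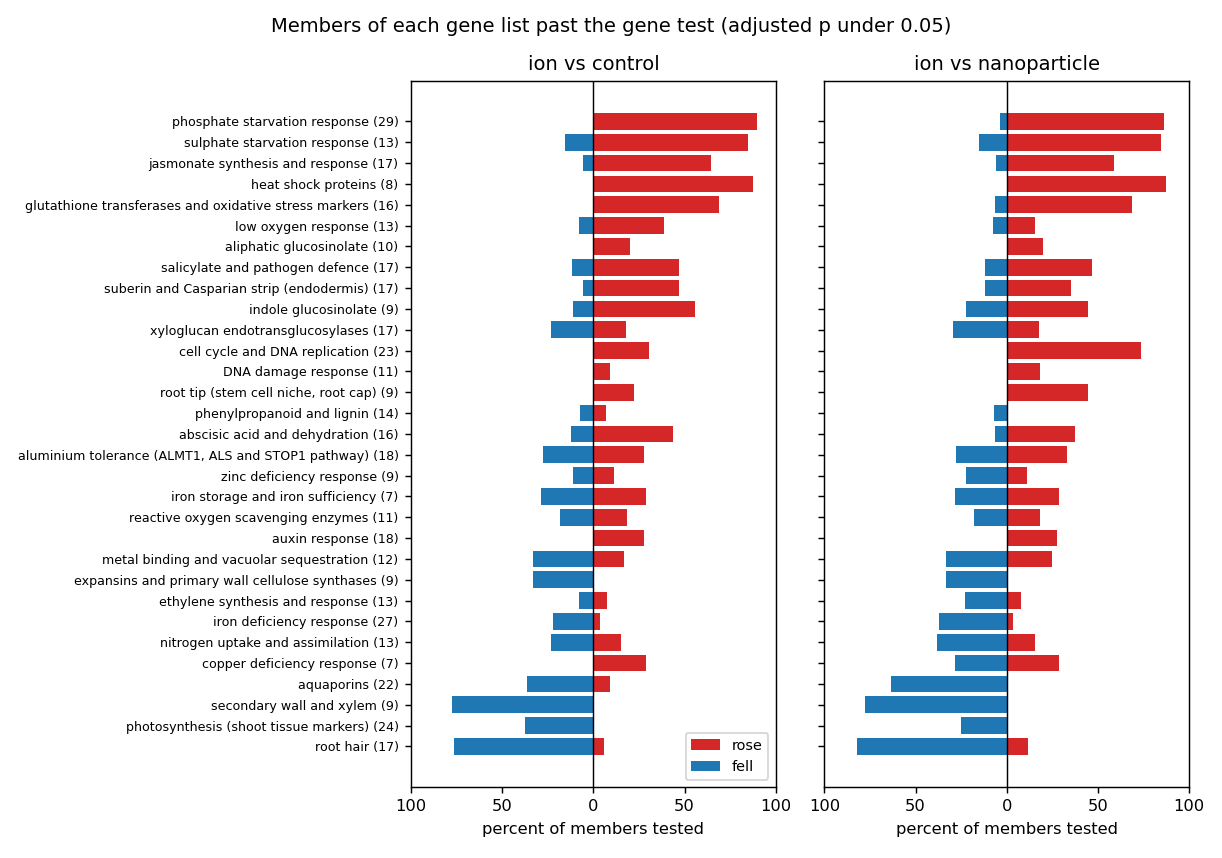
Percent of the tested members of each of 31 gene lists (number tested in brackets) that rose (right) or fell (left) past the limma gene test in ion against control and ion against nanoparticle, each axis running from 0 to 100 percent either way. Phosphate starvation has 26 of 29 members up in the first comparison and 25 in the second, and root hair 13 and 14 of 17 down.

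Other lists held members that moved without a camera call in ion against control. The abscisic acid list had 7 rises and 2 falls in 16 (median 0.35, adjusted p = 0.167), including KIN1 (4.74 ± 0.68, limma adjusted p = 0.0046). The indole glucosinolate list had 5 and 1 in 9 (median 0.66, adjusted p = 0.284) and the auxin list 5 and 0 in 18 (median 0.17, adjusted p = 0.278). The xyloglucan endotransglucosylases had 3 and 4 in 17 (median 0.59, adjusted p = 0.635), where XTH9 rose (1.7 ± 0.17, adjusted p = 0.00115) and XTH14 fell (-3.11 ± 0.41, adjusted p = 0.00324). Expansins and primary wall synthases had 0 and 3 in 9 (median -0.08, adjusted p = 0.278). The scavenging enzymes had 2 and 2 in 11 (median 0.28, adjusted p = 0.64), with superoxide dismutase FSD1 up (2.79 ± 0.29, adjusted p = 0.00133) and catalase CAT2 down (-2.04 ± 0.26, adjusted p = 0.00284). Metal binding and sequestration had 2 and 4 in 12 (median 0.01 but mean -0.15 and test direction down, adjusted p = 0.566). Iron storage had 2 and 2 in 7 (median 0.32, adjusted p = 0.904), zinc deficiency 1 and 1 in 9 (median 0.33, adjusted p = 0.904), and copper deficiency 2 and 0 in 7 (median -0.49 but mean 0.34 and test direction up, adjusted p = 0.904). Ethylene had 1 and 1 in 13 (median -0.16, adjusted p = 0.573) and DNA damage 1 and 0 in 11 (median 0.42, adjusted p = 0.13). Root tip had 2 and 0 in 9 (median 0.42, adjusted p = 0.154), phenylpropanoid 1 and 1 in 14 (median 0.36, adjusted p = 0.438) and aliphatic glucosinolate 2 and 0 in 10 (median 0.91, adjusted p = 0.138). Low oxygen genes did get a camera call (5 and 1 in 13, median 1.1, adjusted p = 0.0328, and adjusted p = 0.728 with an estimated correlation), with HRE2 up (2.73 ± 0.23, limma adjusted p = 0.000771) and HRE1 down (-2.39 ± 0.25, adjusted p = 0.00141), but lost it without control replicate 1 (adjusted p = 0.113) and ion replicate 2 (0.208). Adjusted over the list alone these 16 lists kept their counts except abscisic acid (7 and 3), indole glucosinolate (5 and 2), xyloglucan endotransglucosylases (4 and 4), scavenging enzymes (4 and 2), metal binding (3 and 4), phenylpropanoid (0 and 1), root tip (3 and 0) and low oxygen (6 and 1). Of 26 mitochondrial genes 10 rose and 0 fell (median 0.73), and of 10 plastid genes 2 rose and 0 fell (median 0.98). Most of these small counts moved by over 1.5 times when a library was left out. Without ion replicate 2 the rises were 3 for abscisic acid, 2 for low oxygen and 0 for auxin, indole glucosinolate and aliphatic glucosinolate, and expansins had 0 falls. Without ion replicate 1 auxin had 1 rise, metal binding 0 falls and iron storage 0 rises. Without either nanoparticle library indole glucosinolate and low oxygen had 3 rises each. Without control replicate 1 there were 8 rises for xyloglucan endotransglucosylases, 7 for phenylpropanoid and 6 for aliphatic glucosinolate. Camera called expansins lower (0.0358) and DNA damage higher (0.0459) without control replicate 2, DNA damage also with the length and GC correction (0.0453), and aliphatic glucosinolate higher without ion replicate 1 (0.00463).

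Ionic aluminium against nanoparticles tested the difference between the 2 treatments itself. ALMT1 stood at 239 ± 10 RPKM in ion and 1.12 ± 0.308 in nanoparticle roots (212-fold, log2 fold change 6.82 ± 0.2, limma adjusted p = 2.61e-05). The phosphate gene IPS1 (8.31 ± 0.2, adjusted p = 1.56e-05) and the sulphate gene SDI1 (5.69 ± 0.24, adjusted p = 7.18e-05) were higher in ion. IRT1 (30.4 ± 2.45 against 0.0947 ± 0.134 RPKM, -4.85 ± 0.46, adjusted p = 0.000893), NRT2.1 (-6.18 ± 0.57, adjusted p = 0.000807) and PIP2;4 (-5.74 ± 0.61, adjusted p = 0.00131) were lower. In the aluminium tolerance list 6 rose and 5 fell of 18, also adjusted over the list alone (median 0.13, camera adjusted p = 0.789, fry 0.00856). MATE (1.87 ± 0.35, adjusted p = 0.0107), ALS1 (1.2 ± 0.2, adjusted p = 0.00763) and STOP2 (0.84 ± 0.22, adjusted p = 0.0335) rose and STAR1 (-0.81 ± 0.23, adjusted p = 0.044) and STOP1 (-0.86 ± 0.23, adjusted p = 0.0388) fell, while ALS3 did not pass (0.06 ± 0.23, adjusted p = 0.876). These 5 calls were lost without either nanoparticle library, at 1.84 and 1.91 for MATE, 1.29 and 1.12 for ALS1, 0.72 and 0.96 for STOP2, -0.94 and -0.67 for STAR1, and -0.87 and -0.84 for STOP1. All but MATE were also lost without ion replicate 2, and STOP1, STOP2 and STAR1 without ion replicate 1. With no filter STOP1 (-0.86), STOP2 (0.84) and STAR1 (-0.81) were lost, as was STAR1 without the trend (-0.81). Other scalings ended STOP2 (0.71 with median-of-ratios, 0.8 with TPM and 0.74 with quantile normalization) and STOP1 (-0.87 with quantile normalization). The list had 3 rises and 2 falls without nanoparticle replicate 1, 3 and 1 without nanoparticle replicate 2, 5 and 2 without ion replicate 1, and 4 and 1 without ion replicate 2.

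**Figure D5:**
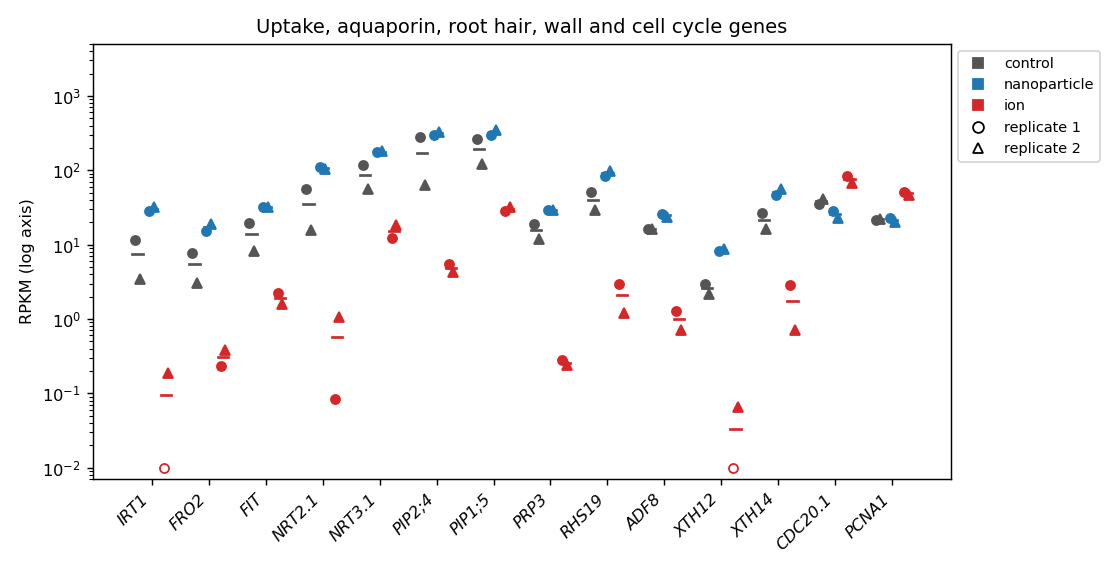
RPKM on a log axis for uptake, aquaporin, root hair, wall and cell cycle genes, with 1 point per library and a bar at the group mean; an open point drawn at 0.01 marks 0 reads. IRT1 averages 7.55 RPKM in control, 30.4 in nanoparticle and 0.0947 in ion.

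Of 29 phosphate genes 25 were higher and 1 lower in ion than in nanoparticle roots (26 and 3 adjusted over the list alone; median 2.47, camera adjusted p = 1.09e-13, fry 0.00318), and adjusted p = 0.478 with an estimated correlation. Of 13 sulphate genes 11 were higher and 2 lower, also adjusted over the list alone (median 2.21, or 3.01 with members at 0 reads at their bound, camera adjusted p = 2.86e-05, fry 0.000946), and adjusted p = 0.478 with an estimated correlation. Root hair genes had 14 lower and 2 higher of 17, also adjusted over the list alone (median -2.97, or -3.09 at the bound, camera adjusted p = 9.53e-09, fry 0.00986), and adjusted p = 0.478 with an estimated correlation, with RHS19 at 90.5 ± 9.82 RPKM in nanoparticle and 2.07 ± 1.22 in ion. Aquaporins had 14 lower and 0 higher of 22, also adjusted over the list alone (median -2.1, camera adjusted p = 3.5e-06, fry 0.0676), and adjusted p = 0.543 with an estimated correlation. Iron deficiency genes had 10 lower and 1 higher of 27, also adjusted over the list alone (median -0.43, camera adjusted p = 0.000305, fry 0.0699), and adjusted p = 0.543 with an estimated correlation. Nitrogen genes had 5 lower and 2 higher of 13, also adjusted over the list alone (median -0.87, camera adjusted p = 0.016, fry 0.2), and adjusted p = 0.597 with an estimated correlation. The iron and the nitrogen camera calls ended without ion replicate 1 (adjusted p = 0.0925 for both). The aquaporin falls were 6 and 5 without nanoparticle replicate 1 and 2 and 4 and 7 without ion replicate 1 and 2. Nitrogen had 2 falls without either nanoparticle library or ion replicate 1 and 8 without either control library. The single phosphate fall went to 0 without either nanoparticle library or ion replicate 1, and the rises of root hair genes to 0 without nanoparticle replicate 2. Iron and nitrogen genes had 0 rises without either nanoparticle library or ion replicate 2.

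Cell cycle genes were higher in ion, with 17 of 23 up and 0 down (20 adjusted over the list alone; median 1.05, camera adjusted p = 2.64e-06, fry 0.0243), and adjusted p = 0.536 with an estimated correlation. CDC20.1 stood at 76.6 ± 11.9 RPKM in ion and 25.6 ± 4.09 in nanoparticle (1.54 ± 0.21, limma adjusted p = 0.00321). Of 9 root tip genes 4 were higher and 0 lower (5 adjusted over the list alone), including the stem cell gene WOX5 (1.18 ± 0.21, adjusted p = 0.00931). The median was 0.52 (camera adjusted p = 0.0491, fry 0.0676), and adjusted p = 0.543 with an estimated correlation. That camera call was lost without control replicate 1 (0.0601) and 2 (0.06), nanoparticle replicate 2 (0.0623) and ion replicate 2 (0.109). It was also lost with no filter (0.0761), a filter at RPKM 5 (0.0988), only the 2 groups compared (0.0597), the length and GC correction (0.0524) and voom (0.0631), and it held under 5 of 16 alternatives. Xylem genes had 7 lower and 0 higher of 9, also adjusted over the list alone (median -1.27, camera adjusted p = 7.68e-05, fry 0.0146), and adjusted p = 0.478 with an estimated correlation. Photosynthesis genes had 6 lower and 0 higher of 24 (7 adjusted over the list alone; median -1.26, camera adjusted p = 1.19e-05, fry 0.213), and adjusted p = 0.597 with an estimated correlation. Without nanoparticle replicate 1 and 2 the cell cycle rises were 3 and 1, xylem had 2 falls in each case, photosynthesis had 20 and 1, and root tip had 0 rises. Without ion replicate 1 and 2 the cell cycle rises were 3 and 5, those of the root tip 1 and 2 and the photosynthesis falls 1 and 1, xylem had 3 falls without ion replicate 1, and WOX5 was lost without either nanoparticle library (1.19 and 1.18).

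Jasmonate genes had 10 higher and 1 lower of 17 (11 and 1 adjusted over the list alone; median 1.35, camera adjusted p = 0.000506, fry 0.00986), and adjusted p = 0.536 with an estimated correlation. Glutathione transferases and oxidative markers had 11 higher and 1 lower of 16, also adjusted over the list alone (median 1.31, camera adjusted p = 0.000506, fry 0.0243), and adjusted p = 0.543 with an estimated correlation. Heat shock genes had 7 higher and 0 lower of 8, also adjusted over the list alone (median 1.41, camera adjusted p = 0.000791, fry 0.00597), and adjusted p = 0.478 with an estimated correlation. Salicylate genes had 8 higher and 2 lower of 17, also adjusted over the list alone (median 0.54, camera adjusted p = 0.0019, fry 0.00509), and adjusted p = 0.478 with an estimated correlation. JAZ1 rose by 2.06 ± 0.17 (limma adjusted p = 0.000557), OXI1 by 2.53 ± 0.21 (adjusted p = 0.00062), HSP70-4 by 3.17 ± 0.26 (adjusted p = 0.000592) and WRKY38 by 4.16 ± 0.26 (adjusted p = 0.000252). Without nanoparticle replicate 1 and 2 the oxidative rises were 6 and 5, those of heat shock 4 and 5, and the jasmonate, salicylate and oxidative falls were 0. Heat shock had 4 rises without ion replicate 1, where the salicylate and oxidative falls were 0, as the oxidative ones were without ion replicate 2.

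Lists without a camera call here included suberin (6 higher and 2 lower of 17, or 7 and 3 adjusted over the list alone, median 0.61, adjusted p = 0.243), although KCS2 rose (2.58 ± 0.2, limma adjusted p = 0.000492). Xyloglucan endotransglucosylases had 3 higher and 5 lower of 17 (median 0.05 but mean -0.52 and test direction down, adjusted p = 0.367), with XTH14 at 51.1 ± 7.37 RPKM in nanoparticle and 1.77 ± 1.5 in ion (-4.34 ± 0.41, adjusted p = 0.000882). The median and the test also differed in direction for phenylpropanoid (0 higher, 1 lower of 14, median 0.06, mean -0.2, adjusted p = 0.466) and iron storage (2 and 2 of 7, median 0.51, mean 0.07, adjusted p = 0.864). In the copper list FSD1 rose (2.67 ± 0.29, adjusted p = 0.00136) and the copper transporter COPT2, at 5.5 ± 3.1 RPKM in nanoparticle, had 0 reads in ion (at least 31.1-fold lower, adjusted p = 0.0115), a call lost without nanoparticle replicate 2 (-2.11) and without either ion library (-2.61). The 11 remaining lists had adjusted p from 0.0552 (DNA damage, 2 higher and 0 lower of 11, or 6 and 0 adjusted over the list alone) to 0.789 (scavenging enzymes, 2 and 2 of 11). Camera called DNA damage higher without ion replicate 2 (0.0268), with no filter (0.0259), with median-of-ratios scaling (0.0356) and with the length and GC correction (0.0407). It called expansins lower without nanoparticle replicate 2 (0.037), low oxygen higher without ion replicate 1 (0.0128), and abscisic acid higher without nanoparticle replicate 2 (0.0329) and ion replicate 1 (0.041). Suberin had 3 rises without nanoparticle replicate 2 and 0 falls without any single nanoparticle or ion library, and 5 falls without either control library.

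In all, 4969 genes passed in limma between ion and nanoparticle (2622 higher and 2347 lower), 3477 of them at least 2-fold. With median-of-ratios scaling 41.3% of the called genes were higher in ion instead of 52.8%, and the median of all genes moved from 0.131 to 0.004 on the log2 scale. The largest falls not named above were in AT5G26130 (389.9 and 423.2 RPKM in nanoparticle, 0 reads in ion, at least 1800-fold lower), AT5G38930 (0 reads in ion, at least 623-fold lower), AIR1 (-6.68 ± 0.5), AT5G46890 (-6.56 ± 0.62), AT1G33840 (0 reads in ion, at least 449-fold lower, within the run of low loci on chromosome 1), AT5G56100 (-6.1 ± 0.25) and UMAMIT17 (-6.08 ± 0.18). Besides IPS1 and ALMT1, given above, the largest rises were again in AT5G20790 (8.1 ± 0.2), PS2 (7.83 ± 0.23), ARD3 (7.58 ± 0.33), HOL2 (6.71 ± 0.57) and AT5G38910 (6.6 ± 0.34), and PEPC1 stood at 151 ± 39 RPKM against 0.0595 ± 0.0841, where it had 2 reads. The number called was 8055 with only these 2 groups in the fit, 8277 with library weights, 8101 and 8068 without control replicate 1 and 2, 1825 and 1351 without nanoparticle replicate 1 and 2, and 2183 and 2428 without ion replicate 1 and 2.

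Nanoparticles against control asked which root transcripts respond to the particles, and no gene passed the test. Aluminium tolerance genes lay close to control, with ALMT1 at 1.12 ± 0.308 against 1.02 ± 0.137 RPKM (0.06 ± 0.2, limma adjusted p = 0.903), MATE at 2.13 ± 0.103 against 1.87 ± 0.435 (0.13 ± 0.35, adjusted p = 0.885) and STOP1 at 117 ± 2.12 against 150 ± 42.5 (-0.32 ± 0.23, adjusted p = 0.614). ALS3 (0.29 ± 0.23), ALS1 (-0.35 ± 0.2), STAR1 (0.53 ± 0.23) and STOP2 (-0.35 ± 0.22) had limma adjusted p of 0.595 to 0.63. The list had a median of 0.06 over 18 members (camera adjusted p = 0.663, fry 0.893). In limma 0 of 19648 genes passed, the smallest adjusted p being 0.595, and 1307 genes had an unadjusted p under 0.05. By the other tool run, voom on the recovered reads, 0 were called. Without control replicate 2 limma called 0 genes, and without control replicate 1 it called 3426 (2018 higher and 1408 lower), 1798 of them at least 2-fold. That omission left 4 members of the aluminium list higher and 1 lower, including STAR1 (0.79) and STOP1 (-0.61). With the length and GC correction as well, 2767 genes were called without control replicate 1.

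The genes with the smallest p, all of which miss the threshold at a limma adjusted p of 0.595, were AT5G26130 (389.9 and 423.2 against 166.3 and 141 RPKM), the phosphate transporter PHT1;3 (24.7 ± 6.33 against 5.83 ± 2.11), UMAMIT35 (11.4 ± 2.53 against 2.63 ± 0.965), XTH12 (8.47 ± 0.492 against 2.6 ± 0.557) and AT5G65980 (25.5 ± 3.5 against 8.74 ± 0.62) on the higher side. On the lower side they were AT3G18250 (9.72 ± 2.03 against 35.8 ± 6.71 RPKM), AT1G20065 (1.18 ± 0.121 against 5.05 ± 1.65), GCL1 (9.44 ± 0.209 against 17.5 ± 0.705), AT2G40205 (19.2 ± 2.04 against 36.6 ± 6.32) and the defence peptide gene PROPEP4 (4.5 ± 0.681 against 10.9 ± 3.18).

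Camera called 10 lists higher and 2 lower in nanoparticle than in control roots, with 0 members past the gene test. Root hair genes had a median of 0.7 over 17 members (camera adjusted p = 6.94e-08, fry 0.667), 3 of them higher when adjusted over the list alone, for example RHS19 at 90.5 ± 9.82 against 40.3 ± 15.1 RPKM. Aquaporins had 0.86 over 22 (2.18e-07), iron deficiency genes 0.62 over 27 (9.24e-06; 3 higher adjusted over the list alone) with IRT1 at 30.4 ± 2.45 against 7.55 ± 5.86 RPKM. Xyloglucan endotransglucosylases had 0.83 over 17 (9.24e-06; 8 higher adjusted over the list alone) and nitrogen genes 0.87 over 13 (0.000341) with NRT2.1 at 108 ± 4.39 against 35.6 ± 28.4 RPKM. Phenylpropanoid (0.47 over 14, adjusted p = 0.000416), suberin (0.31 over 17, adjusted p = 0.000542), low oxygen (0.56 over 13, adjusted p = 0.014), expansin (0.36 over 9, adjusted p = 0.0317) and aliphatic glucosinolate genes (0.35 over 10, adjusted p = 0.0438) also lay higher. Cell cycle genes (-0.41 over 23, adjusted p = 3.87e-05), such as CYCB2;1 at 4.5 ± 0.823 against 9.78 ± 2.64 RPKM, and photosynthesis genes (-0.52 over 24, adjusted p = 0.0164) lay lower. Each of these 12 lists had an adjusted p = 0.727 with an estimated correlation, and fry gave 0.667 to 0.72.

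The control libraries themselves differed in most of these lists. Control replicate 2 lay below control replicate 1 by mean log2 differences of -0.64 over root hair, -1.16 over aquaporin, -1.04 over nitrogen, -0.39 over iron deficiency, -0.42 over xyloglucan endotransglucosylase, -0.66 over expansin, -0.65 over phenylpropanoid and -0.73 over aliphatic glucosinolate genes, and above it by 0.19 over cell cycle genes. Without control replicate 2 the medians against the remaining control library were 0.56 for root hair (camera adjusted p = 4.08e-07), 0.31 for aquaporins (0.00185), 0.35 for iron deficiency (2.28e-06), 0.46 for xyloglucan endotransglucosylases (2.53e-06), 0.36 for nitrogen (0.00312) and -0.27 for the cell cycle (3.22e-05). The calls of phenylpropanoid (0.0918), expansin (0.497) and aliphatic glucosinolate genes (0.876) ended there, the last also without nanoparticle replicate 1 (0.116), with no filter (0.0838) and with median-of-ratios scaling (0.0631), and secondary wall genes were called lower (0.00282). Low oxygen (0.382) and photosynthesis (0.314) ended without control replicate 1, a filter at RPKM 5 ended expansin (0.133) and photosynthesis (0.142), and the photosynthesis list turned to higher without nanoparticle replicate 1 (7.75e-04). Without control replicate 1 the gene test called 15 of the 22 aquaporins, 9 of the 14 phenylpropanoid, 8 of the 17 xyloglucan endotransglucosylase, 7 of the 17 root hair and 8 of the 13 nitrogen genes higher, and 6 of the 23 cell cycle genes lower and 1 higher. Of the iron deficiency genes 7 were then higher and 1 lower, 4 expansin and wall synthase genes were higher, and 4 suberin genes were higher and 1 lower.

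The 19 other lists had no camera call in this comparison, with adjusted p from 0.137 (phosphate, median 0.07, and copper, median 0.17) to 0.964 (scavenging enzymes, median 0.03). Sulphate genes had a median of 0 (adjusted p = 0.548), heat shock genes -0.04 (adjusted p = 0.634), jasmonate genes -0.13 (adjusted p = 0.663) and salicylate genes -0.07 (adjusted p = 0.664). 1 copper gene was higher when adjusted over the list alone, and DNA damage had a median of -0.25 but a mean of 0. Without nanoparticle replicate 1 camera called copper (0.0141) and phosphate genes (0.0444) higher, and copper genes also with no filter (0.0149). The gene test without control replicate 1 called 4 genes higher in each of the phosphate list and the list of glutathione transferases and oxidative markers.

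No gene was called the same way in both treatments against control by limma, since the nanoparticle comparison called 0. Unchanged groups sharing the control libraries gave 0.01 such genes on average in 100 simulations. Across genes, the log2 fold changes of both treatments correlated at 0.14, against 0.77 simulated for unchanged groups sharing controls. These 2 correlations cannot be compared, because the simulated groups carry no treatment effect, while the ion changes had an SD of 0.956 over genes. The covariance of the log2 fold changes was 0.056 against a simulated 0.073, a difference of -0.017. The simulation drew from the moderated spread of each gene, and the measured difference between these control libraries implies a larger shared covariance, 0.101, so the size of that difference is not settled. The correlation was -0.01 without control replicate 2 and 0.43 without control replicate 1. Without control replicate 1, 2058 genes were called the same way (1335 higher and 723 lower) and 217 in opposite directions. With 2 control libraries, no split that keeps 2 in each part was possible, so part of any overlap may come from the shared controls.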

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

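The length and GC correction and voom on the recovered reads were chosen after the data were seen. The 2 groups compared alone gave 2758 genes for ion against control and 8055 for ion against nanoparticle, and library quality weights (0.38 for each control library, 2.63 for each nanoparticle library and 0.99 for each ion library) gave 2904 and 8277. Median log2 fold changes over all genes stayed at 0.062 and 0.131. These counts therefore turn on the estimated spread and its degrees of freedom. The main fit takes 1 spread per gene for all groups, while the SD between libraries was 0.45 in control, 0.19 in nanoparticle and 0.298 in ion. The nanoparticle libraries thus lower the spread used for ion against control. The control libraries raise that used for ion against nanoparticle. Leaving out 1 library at a time gave 0 to 3426 genes for nanoparticle against control, 1865 to 7732 for ion against control, 1351 to 8101 for ion against nanoparticle, and 0 to 2058 changed the same way by both treatments. The 3426 and 2058 came without control replicate 1, in which the lone control library is assumed to vary as little as the other groups. With an estimated correlation, camera called 0 lists in each of the 3 comparisons, against 12, 13 and 14 at the preset correlation. That form of the test rests on 3 residual degrees of freedom and can call little. In ion against control the sulphate list had an estimated correlation of -0.01, below the preset 0.01. Its camera adjusted p still went from 1.32e-05 to 0.46. The loss of calls therefore cannot tell whether genes that vary together gave them. All other alternatives for the counts of genes and lists stayed within 1.5 times, with voom at 0, 4647 and 5090 genes and the length and GC correction at 0, 4679 and 5563. No list that was called changed direction with median-of-ratios scaling or quantile normalization, and lists were not tried with TPM.

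No strong effect shared by libraries of the same replicate number was seen, which does not exclude a pairing. Deviations of same-numbered libraries correlated at -0.054, -0.164 and 0.075 across genes. With the replicate block limma called 0, 3733 and 4043 genes and camera 11, 13 and 13 lists. The block ended the camera calls of the aliphatic glucosinolate list in nanoparticle against control (0.0597) and of the root tip list in ion against nanoparticle (0.055). It also ended the limma calls of STAR1 (-0.81) and STOP1 (-0.86) in the latter.

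Of the named genes, 38 of 115 for ion against control and 47 of 128 for ion against nanoparticle missed the threshold under at least 1 alternative, 13 and 10 of them outside the omission of a library, and 0 reversed. In the nanoparticle comparison 40 of 63 passed without control replicate 1. Depth limits genes near the floor of 3 reads, and the simulated recovery of 16.7% of 2-fold changes limits the nanoparticle comparison. Simulated false calls above the share that the adjusted p threshold allows limit the count of genes for ion against control.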

Other observations

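The tests on length and GC content, on ion RNA in control replicate 2, on root zones, on the 3 YABBY genes and on runs of neighbouring loci were chosen after the results were seen, while the tests on neighbours at 0 reads, on a graded fall and on shoot identity were written before.

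Some transcripts were detected in the ion libraries alone. 8 genes with at least 100 reads over the ion libraries had 0 reads in all 4 control and nanoparticle libraries, and all are named from their values. AT3G25240 had 529 and 652 reads in ion, at least 417-fold above control. MIR827, the precursor of a microRNA of phosphate starvation, had 79 and 86 reads (at least 58.3-fold), and the tonoplast aquaporin TIP1;3 had 62 and 61 (at least 43.5-fold). The others were AT5G16740, AT4G19730, AT2G36724, AT1G71140 and AT2G05660.1, the last with 751 reads in ion replicate 1 and 0 in ion replicate 2. AT2G04460.1 had 718 and 798 reads in ion and 1 read over the other 4 libraries. It was 1 of 57 genes with at least 100 ion reads and 1 to 20 reads over those 4 libraries. The 8 genes thus lie at the end of a range of low counts.

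Genes of the organelle genomes were higher in ion than in nanoparticle libraries too, with 10 of 26 mitochondrial genes past the limma test (median 0.91 on the log2 scale) and 4 of 10 plastid genes (median 1.05), and 0 lower in either. Against control, the nanoparticle libraries had 0 of 26 and 0 of 10 past it by limma, with medians of -0.01 and -0.2. Reads of ribosomal RNA genes were higher in the same libraries, at 0.247% and 0.275% in ion against 0.004% to 0.118% in the other 4, so a difference in RNA selection or quality stays open and was not tested.

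Control replicate 2 stood apart from control replicate 1. Values went against 2 explanations: length and GC content as the sole cause, and ion RNA. Transcript length and GC content took up 15.1% of the variance of the difference between these libraries. Its SD over genes stayed at 0.58 after the correction (0.63 before), above the 0.41 between the ion libraries. Before the correction, length and GC content took up 14.9% of the variance of control replicate 2's deviation from the gene means, against 0.7% to 2.4% in the other libraries. Ribosomal RNA genes held 0.004% of its reads and 0.109% of those of control replicate 1. A difference in RNA selection or quality thus stays open here too and was not tested. Ion RNA mixed into control replicate 2 would raise the genes with the largest ion rise, and the median over 8 of them of control replicate 2 minus control replicate 1 was -0.097% of the ion level, the highest being 0.035%. Another makeup of root zones may still account for it: after the correction root hair genes differed by -0.55 ± 0.16, aquaporins by -1.09 ± 0.14 and root tip genes by 0.44 ± 0.14 (SE over genes), yet the cell cycle genes, which that explanation needs to be higher, differed by 0.09 ± 0.11, which decides nothing. The design offers no biological difference between libraries of 1 group, so none was tested.

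Of 16230 genes with at least 100 reads in control and as many in nanoparticle, 18 had 0 reads in both ion libraries. A graded fall could give most of them, since 69 genes had 1 to 10 ion reads and 256 had 11 to 50. For 4 of the 18 the nearest expressed neighbour was at 0 in ion too, as a deletion in the ion plants would give. In 100 random draws of as many genes, which treat genes as independent, the count was at most 1 (0.09 on average). Of these 4, AT1G33840, AT1G33870 and AT1G33900 lie in the run described next, and AT1G63570 lies outside it. The count and the run are thus largely the same evidence. The longest run anywhere of loci at 5% or less of the level of the other libraries was 6, against 3 in 100 random orders of 20505 loci. These orders treat loci as independent. Over the genome there were 5 runs of 3 or more such loci, those in the stretch named next included. On chromosome 1, 10 of 11 neighbouring expressed loci from AT1G33813.1 to AT1G33930 held 5% or less of that level. The exception, AT1G33890, kept 8 and 6 ion reads, or 16.23%. AT1G33810 and AT1G33970 on either side of the run stood at 99.74% and 55.76%. A deleted or diverged stretch in the ion plants is a hypothesis for this run, and a shared loss of expression there under ionic aluminium remains open and untested, since no sequence was analysed here, so the 4446 and 4969 genes called in the ion comparisons could include some that differ by genotype or seed stock.

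Photosynthesis genes were low in nanoparticle replicate 1 and in both ion libraries, all 24 being higher in nanoparticle replicate 2 than in replicate 1, and length and GC content do not account for this, since the median difference was 1.43 on the log2 scale after the correction and 1.45 before, whereas shoot tissue in some libraries could. The test written before, on 9 shoot identity genes, gave a ratio of 1.03 between the nanoparticle libraries (95% exact binomial interval 0.92 to 1.14, two-sided exact binomial p = 0.643), which met the bound set against that explanation. That bound was wrong, which was decided after the value was seen, because PDF1, with a high baseline in every library, made up 92.6% to 98% of the reads summed. The shoot genes FIL, YAB2 and YAB3, picked from the 9 after the results were seen, together had 6 and 5 reads in control. They had 0 and 8 in nanoparticle (two-sided exact binomial p = 0.00784) and 0 and 2 in ion. Other members were not lowest in ion. TMM had 2 and 2 reads in control, 3 and 2 in nanoparticle and 23 and 15 in ion. CER1 had 12 and 6, 9 and 14, and 15 and 10 in the same order, and SPCH 0 and 0, 1 and 3, and 5 and 1. FAMA and GL1 had 0 to 3 reads in each library. These reads are too few and too mixed to decide, so shoot tissue stays open. An effect of the treatments would not give the difference between the nanoparticle libraries if both had the same exposure. The labels do not establish that, since doses and times are not given and those of nanoparticle replicate 2 spell the compound nAl2O4. For the ion libraries a treatment effect stays open and untested.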
